A study of Mus musculus with 20 samples.

How the data were processed

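RNA sequencing of flow-sorted male germ cells of mice was analysed for 20 libraries in 6 groups: heterozygous and knockout for Tex15 at e16.5 and e18.5 (3 libraries each) and at d2 (4 each). The series text speaks of triplicates, while d2 holds 4 libraries per genotype. The labels give total RNA, a mixed strain background, sorting by green fluorescence and Ovation amplification kits. The labels do not say whether replicates are separate animals, so p-values measure the spread between these samples only.

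The deposited tables hold counts, raw and unscaled, for each gene symbol and each repeat name per library. A second deposited table per age holds expected_counts, estimated counts per repeat family that are not all whole (66.0% of values at e16.5, 70.1% at e18.5 and 65.6% at d2 are not whole numbers) and are not scaled. Per the labels the authors used STAR, featureCounts, edgeR and Bowtie with the mouse build mm9, with no versions, roles or order given. How reads in several places were counted and whether strand was used are not stated, so overlapping or antisense genes and near-identical genes can share reads. The tables held 24495 gene symbols at e16.5 and e18.5 and 24341 at d2, of which 23853 were common to all. Each also held 1217 repeat names, and 52 named families stood in the family tables.

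Gene and repeat rows of each table were separated by name. Total counts per library ran from 14.3 to 31.5 M (mega), of which 7.78 to 14.2 M were counted in genes. Values are given as CPM (counts-per-million) of the gene counts times their TMM factor. Repeat names and families used the same library sizes, so that a change in many repeats at once was not scaled away. CPM of repeats are thus relative to gene counts, not to all counts. Intervals of ratios (95%, exact binomial) and the floor of 3 counts over a group cover counting error only.

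Each age was fitted alone with edgeR 4.0.16 in R 4.3.3: filterByExpr (at least 10 counts, 15 in total), TMM factors, a robust quasi-likelihood fit on genotype and its F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Repeat families, and repeat names in a test added after the tables were seen, went through the same fit. A joint fit of all 20 libraries on the 23853 common symbols tested whether the knockout effect differed between ages and how heterozygous cells changed with age. The share of counts in repeats was compared with a two-sided exact permutation test. Overlaps of called genes used Fisher's exact test.

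Gene lists (24) were tested with camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 and with an estimated one, adjusted over all lists and the 3 ages. They were the piRNA pathway, DNA methylation machinery, heterochromatin and histone-based repeat silencing, fetal prospermatogonia, pluripotency and primordial germ cells, spermatogonial stem and progenitor cells, meiotic prophase, homologous recombination repair, germline genes with methylation-controlled promoters, imprinted genes, cleavage-stage and MERVL-linked genes, cell proliferation, p53 targets and apoptosis, interferon and nucleic acid sensing, dissociation and stress genes, cytoplasmic ribosomal proteins, spermiogenesis and post-meiotic genes and mitochondrially encoded genes. Markers of Sertoli, Leydig, stroma, endothelial, macrophage and white blood, and red blood cells made up the rest. Repeat names were grouped as young L1, IAP, MusD and ETn, MERVL, other retroviruses, SINEs, satellites and DNA transposons.

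Named genes are Tex15 and, per knockout comparison, up to 10 increases and 10 decreases with the largest change among called genes with no overlap between genotypes and a mean log2 CPM of at least 1, leaving out symbols of the Gm and Rik kind. From each gene list up to 3 called members with the smallest p were added, or up to 2 given as values where none was called. Repeat names are the 12 with the smallest p and the most abundant L1 and IAP names. The age comparisons name 6 genes per direction with a mean log2 CPM of at least 3, and the interaction tests 5 genes each. The groups, tests, lists, naming rules and the first set of alternative settings were fixed before the data were examined. GSAT_MM, IAPEz-int and L1Md_A at ages where the rule did not name them, and the L1 and Satellite families where they did not pass, were added after their values were seen. Other families and L1 names that had at first been added in the same way were dropped after it was seen that some changes near 0 turned in direction under other scalings.

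That first set was DESeq2 1.42.0, median-ratio factors, no filter, a filter at 1 CPM, voom with quality weights, a block for the replicate number, all ages in 1 fit, the repeats' own scaling and leaving out each library. Added after seeing the data were genes and repeats in 1 fit, the stroma marker level as a covariate and the fits of repeat names. On simulated data with the same depth and spread, edgeR recovered 49.0%, 52.0% and 59.6% of genes changed 2-fold at e16.5, e18.5 and d2, and 90.0%, 93.0% and 87.0% of those changed 4-fold, with 13, 4 and 4 unchanged genes called. The joint fit recovered 29.0% of 2-fold and 85.0% of 4-fold differences between ages. The changed genes were drawn only from those with a mean log2 CPM of at least 1, so recovery at lower levels was not measured. In the simulated lists camera called the changed list with both settings, and the preset correlation also called 1, 2 and 1 other lists at e16.5, e18.5 and d2, which can share genes with it. Simulated genes were drawn independently of each other, so these lists cannot show which correlation setting suits the real data. For the closing tests gene length was that of the longest GENCODE M21 transcript and gene order came from RefSeq on GRCm38, both matched by symbol or by a single synonym. Genes without a length stayed in that fit uncorrected, and genes without a position were left out of the neighbour test. Figures were drawn with matplotlib 3.10.9. No library was left out of the reported values, and no raw reads were analysed here.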

Results

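RNA was sequenced from male germ cells of mice, sorted by green fluorescence, that carried 1 working copy of Tex15 (heterozygous) or none (knockout). Tex15 is a germ cell gene whose loss is known to cause male infertility. The cells came from embryonic days 16.5 (e16.5) and 18.5 (e18.5) and from postnatal day 2 (d2), with 3 libraries per genotype at each embryonic age and 4 per genotype at d2, 20 in all. These ages span the time when fetal male germ cells rest from division and regain DNA methylation. The total count per library was 22.6 to 24.2 M (mega) in heterozygous and 25.4 to 29.7 M in knockout cells at e16.5. It was 26.3 to 31.5 M and 26.9 to 30.3 M at e18.5, and 16.8 to 24.8 M and 14.3 to 24.5 M at d2. Repeats took 55.9% ± 4.31 (SD, n = 3) of the counts in heterozygous and 50.4% ± 4.60 in knockout cells at e16.5, 58.4% ± 3.08 and 61.1% ± 3.43 at e18.5, and 48.0% ± 3.51 and 50.2% ± 3.12 (n = 4) at d2. Values below are counts-per-million (CPM), scaled on the gene counts of each library.

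Tex15 itself was read first, to test the genotype labels. In heterozygous cells it lay at 1590 to 1912 CPM at e16.5, 1312 to 1827 at e18.5 and 633 to 1027 at d2. Knockout libraries held 3.23 to 4.84 CPM at e16.5 and 1.75 to 4.54 at e18.5. At d2 knockout replicates 1, 3 and 4 held 2.07, 2.52 and 2.62 CPM, whereas replicate 2 held 104 CPM from 799 counts, 12.2% of the heterozygous mean. The log2 fold change of Tex15 was -8.82 at e16.5 (adjusted p = 2.1e-10, edgeR) and -8.96 at e18.5 (adjusted p = 7.2e-11). At d2 it was -4.97 with an adjusted p of 0.167, and -8.45 with an adjusted p of 3.1e-14 without knockout replicate 2. Tex15 was lower in each knockout library than in every heterozygous library of its age. Which part of the gene was deleted is not stated, so reads outside that part can remain.

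**Figure D1:**
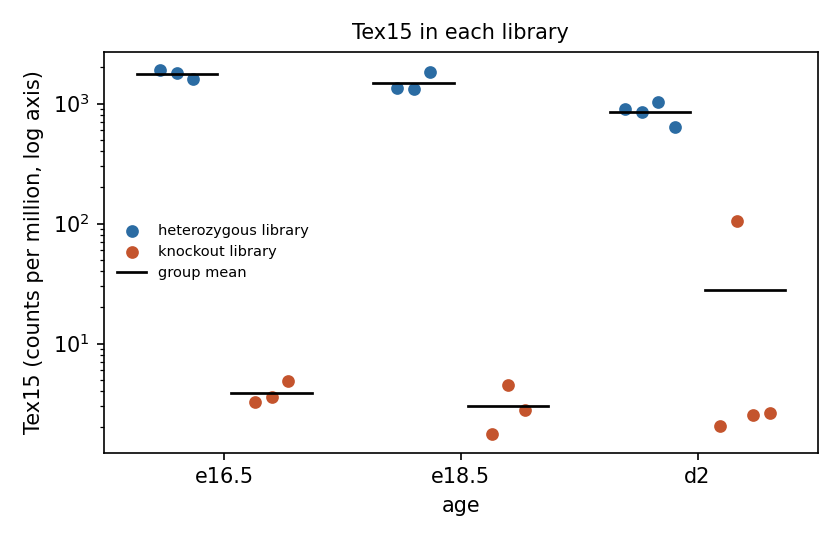
Tex15 level in each library (CPM, log axis) by age and genotype, 1 point per library. Knockout replicate 2 at d2 lies at 104 CPM, while the other knockout libraries lie between 1.75 and 4.84.

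The e16.5 comparison asks what the loss of Tex15 changes in fetal germ cells at the youngest age sampled. Tex15 was the only gene of 16384 that passed the test, and it fell. Among repeats, IAPLTR1_Mm, a long terminal repeat of IAP retrotransposons, rose 1.90-fold, from 103 ± 21.6 to 196 ± 24.5 CPM (SD, n = 3; adjusted p = 0.00376). No retrotransposon of the young L1 group rose or fell: 0 of 6 members passed, with log2 fold changes from -0.27 to -0.05, where the median of all repeat names was -0.27 with gene scaling and 0.0012 when the repeat counts set their own scaling. Beside the 1 gene called by edgeR, 1266 genes had an unadjusted p under 0.05, DESeq2 called 22 genes, and without heterozygous replicate 1 edgeR called 25 (4 higher, 21 lower).

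Of 51 repeat families 0 passed at e16.5 with edgeR and with DESeq2, and 2 had an unadjusted p under 0.05. Without heterozygous replicate 1 the Satellite family alone was called, and it was lower. Of 1113 repeat names, 3 passed. Besides IAPLTR1_Mm these were tRNA-Gly-GGG (log2 fold change -1.63, adjusted p = 0.0248) and FordPrefect_a, a DNA transposon (log2 fold change -1.28, adjusted p = 0.0422), both counted at under 7 CPM. These 2 calls ended with DESeq2, with the repeats' own scaling, with no filter and with the replicate block, as they did in 5 of the 6 fits without 1 library (adjusted p of up to 0.549 and 0.773). IAPLTR1_Mm was 1 of 16 IAP names that rose, while 0 of 5 MusD and ETn names and 0 of 7 MERVL names passed. The IAP body IAPEz-int, named after its values were seen, measured 635 ± 84.6 CPM in heterozygous and 1045 ± 153 in knockout cells and did not pass (adjusted p = 0.0767). It passed with DESeq2 (adjusted p = 0.0191), with the repeats' own TMM factors (adjusted p = 0.0134) and totals (adjusted p = 0.0139), without heterozygous replicate 1 (adjusted p = 0.0425) and without knockout replicate 2 (adjusted p = 0.00835), while its highest adjusted p was 0.773, without heterozygous replicate 3. The most abundant L1 and IAP names, L1Md_F2 (log2 fold change -0.20) and IAP-d-int (log2 fold change -0.09), did not pass, and both signs turned when the repeat counts set their own scaling. The count of 3 became 6 without heterozygous replicate 1, 1 without heterozygous replicate 2, and 0 without heterozygous replicate 3, knockout replicate 1 or knockout replicate 3. The call of IAPLTR1_Mm ended in these last 3 fits, with an adjusted p of up to 0.427.

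Gene lists at e16.5 moved in ways that depended on how the correlation between genes was set. With the preset correlation 7 of the 23 measured lists passed. Cytoplasmic ribosomal proteins (adjusted p = 7.0e-08, median log2 fold change 0.28), the piRNA pathway (adjusted p = 0.000465, median 0.19), heterochromatin and histone-based repeat silencing (adjusted p = 0.00295, median 0.17), fetal prospermatogonia (adjusted p = 0.0125, median 0.23) and cell proliferation (adjusted p = 0.0296, median 0.14) lay higher in knockout cells. Markers of peritubular and interstitial stroma (adjusted p = 9.9e-06, median -0.72) and of Sertoli cells (adjusted p = 0.00539, median -0.56) lay lower. None of the 7 passed with an estimated correlation: the adjusted p was 0.839 for cell proliferation and 0.741 for the other 6. With fry none of the 7 passed either, directional or mixed. No member of any of the 7 passed over all genes. Adjusted over the list alone, 7 of 17 stroma markers fell and 0 members of the other 6 lists passed. Exd1 and Gtsf1, both partners of the piRNA machinery, measured 17.1 ± 3.55 against 29.5 ± 4.81 and 60.7 ± 8.51 against 85.6 ± 6.996 CPM. Nanos2, a regulator of male germ cell fate, measured 6.85 ± 1.11 against 11.3 ± 2.61, and Tex19.1, a germline repressor of retrotransposons, 187 ± 38.0 against 262 ± 29.1. Daxx and Setdb1 measured 12.6 ± 2.35 against 19.3 ± 3.78 and 174 ± 40.4 against 233 ± 27.5.

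Markers of the cells around the germ cells were counted in all e16.5 libraries. Stroma markers summed to 343, 545 and 503 CPM in heterozygous libraries and to 316, 341 and 314 in knockout libraries. The collagens Col1a1 (75.2 ± 15.4 against 48.7 ± 5.14 CPM) and Col3a1 (40.4 ± 18.7 against 16.4 ± 5.72) did not pass (adjusted p = 0.629), although Col3a1 passed without heterozygous replicate 1 (adjusted p = 0.0232). Nor did the Sertoli genes Kitl (4.56 ± 0.326 against 2.19 ± 1.05) and Sox8 (2.31 ± 1.27 against 0.753 ± 0.415). Leydig cell markers summed to 145 CPM in heterozygous replicate 2 and to 53.6 to 63.5 in the other 5 libraries. Without heterozygous replicate 1 the number of lists past the threshold was 12, and it was 4 without heterozygous replicate 3 and without knockout replicate 2.

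At e18.5 more genes rose than fell in knockout cells, and young retrotransposons rose with them. Of 18075 genes, 373 rose and 49 fell, and 126 of the genes that rose lay under 1 CPM in heterozygous cells. Genes that low were tested mainly where their knockout counts passed the filter, so a rise could be seen but hardly a fall. Young L1 retrotransposons (6 of 6), IAP (15 of 16) and MusD and ETn elements (5 of 5) rose, while 0 of 7 MERVL names passed. Gtsf1, a protein that works with piRNA-bound PIWI proteins, fell 3.06-fold, from 86.1 ± 13.05 to 28.1 ± 1.44 CPM (SD, n = 3; adjusted p = 5.6e-06). The heterochromatin protein gene Cbx5 rose 1.72-fold, from 417 ± 61.7 to 716 ± 29.9 CPM (adjusted p = 0.000552). The count of 422 was 152 with all ages in 1 fit (127 higher, 25 lower), 281 without heterozygous replicate 2 and 274 without knockout replicate 2.

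The largest increases at e18.5 were mostly in olfactory and pheromone receptor genes, known from sensory neurons. Olfr419 rose from 2 counts to 332 in the 3 libraries of each genotype, a ratio of 183 (95% counting interval 50.4 to 1520). Olfr1504 (ratio 105, 28.8 to 877), Olfr792 (ratio 76.96, 25.97 to 376) and the chloride channel accessory gene Clca4b (ratio 104, 28.5 to 868) likewise rose from 2 or 3 counts. Adam39, of a family of membrane proteases, had 0 counts in heterozygous cells and was at least 50.4-fold higher, against 3 counts over the group. Olfr11, Olfr731, Olfr418 and the pheromone receptor Vmn1r34 rose with log2 fold changes of 5.64, 4.64, 4.46 and 4.55. Rpe65, a retinal enzyme of the visual cycle, rose with a log2 fold change of 4.49 (0.407 ± 0.508 to 8.61 ± 7.16 CPM), a call that ended without heterozygous replicate 2 (adjusted p = 0.0541). With so few counts in heterozygous cells the size of the change moved with single libraries: without 1 library the log2 fold change ran from 3.54 to 6.10 for Rpe65, 4.97 to 10.8 for Olfr11, 3.92 to 8.36 for Olfr418, 4.201 to 5.38 for Olfr731 and 3.92 to 8.56 for Vmn1r34. The call of Olfr11 ended with DESeq2 (adjusted p = 0.118) and that of Olfr418 with all ages in 1 fit (adjusted p = 0.153). Receptor genes are near-identical, so reads may be shared between them, and their single values are uncertain.

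Genes that fell at e18.5 were fewer. Il5ra, an interleukin receptor chain, fell 13.9-fold, from 29.0 ± 5.15 to 2.08 ± 0.833 CPM (adjusted p = 6.4e-07). Cd160, a surface receptor of lymphocytes, fell 4.14-fold (adjusted p = 0.000318), and Hsf3, a heat shock factor, fell 2.83-fold (adjusted p = 0.00119). Stard4, a carrier of cholesterol, fell 2.45-fold (adjusted p = 0.00466), and Zmat4 fell 2.39-fold (adjusted p = 0.00164). Each of these 5 calls held in all fits without 1 library, but that of Hsf3 ended with all ages in 1 fit (adjusted p = 0.394). Akr1b7, Rgs4 and Ccdc84 also fell (log2 fold changes -1.48, -1.56 and -1.25). Their calls ended in 4, 4 and 3 of the 6 fits without 1 library, with adjusted p values of up to 0.143, 0.147 and 0.172: for Akr1b7 without heterozygous replicates 1 or 2 or knockout replicates 2 or 3, for Rgs4 without replicates 1 or 3 of either genotype, and for Ccdc84 without heterozygous replicate 2 or knockout replicates 2 or 3. These 3 calls also ended with all ages in 1 fit (adjusted p of 0.218, 0.136 and 0.120).

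**Figure D2:**
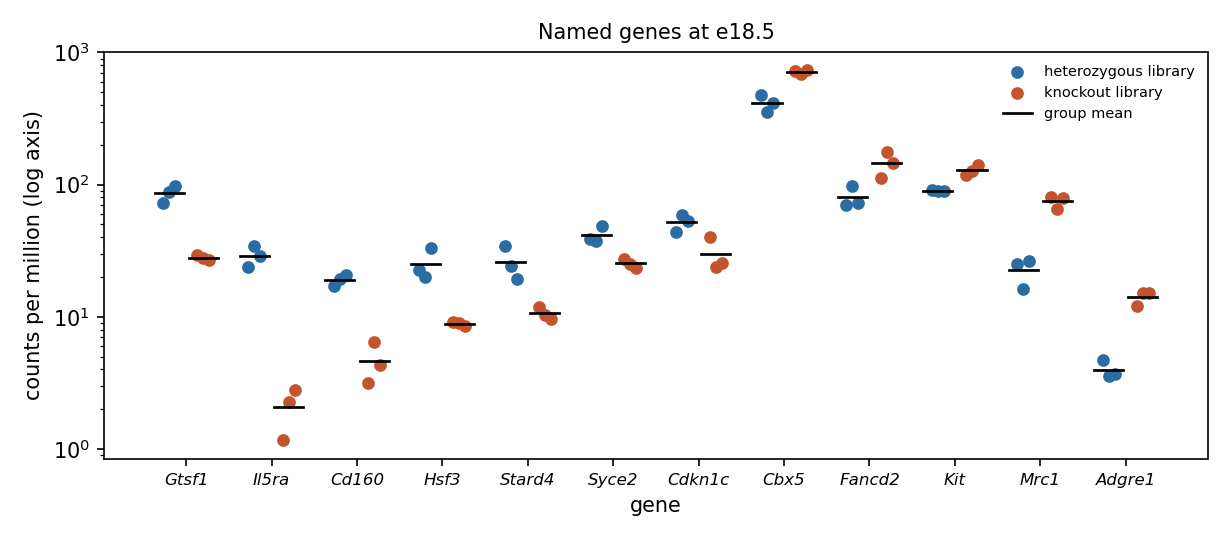
Level of 12 genes at e18.5 (CPM, log axis) in each heterozygous and knockout library, with the mean of each group of 3. Gtsf1 lies at 86.1 CPM on average in heterozygous and 28.1 in knockout cells, and Mrc1 at 22.5 and 75.3.

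Few members of the germ cell lists passed at e18.5. In the piRNA pathway 1 of 25 members passed, Gtsf1. In the heterochromatin list 1 of 20 rose, Cbx5, and in homologous recombination repair 1 of 21 rose, Fancd2, a gene of DNA crosslink repair (80.4 ± 14.7 to 145 ± 32.01 CPM, adjusted p = 0.00629; 0.0803 without knockout replicate 2). Kit, a receptor of germ cells, rose 1.44-fold (adjusted p = 0.0389), 1 of 16 in the pluripotency list. Of 29 meiotic prophase genes 1 fell, Syce2, a part of the synaptonemal complex (41.7 ± 6.22 to 25.3 ± 2.13 CPM, adjusted p = 0.0456). The meiotic list passed with the preset correlation (adjusted p = 0.0106, median log2 fold change -0.18; adjusted p = 0.741 with an estimated correlation). Of 25 imprinted genes 3 fell: Cdkn1c, a growth inhibitor (adjusted p = 0.0407), Zim1 (adjusted p = 0.0428) and Rasgrf1 (adjusted p = 0.0467). The list itself did not pass (adjusted p = 0.0785), and these 3 also fell when adjusted over the list alone. Of 9 cleavage-stage genes 1 rose, Zscan4a, at least 15.1-fold above 0 counts (adjusted p = 0.00822; 0.0512 without knockout replicate 1), a member of a near-identical family whose reads may be shared. The calls of Syce2 and Rasgrf1 ended in all 6 fits without 1 library (adjusted p of up to 0.184 and 0.227), and those of Kit and Zim1 in all but that without heterozygous replicate 3 (up to 0.184 and 0.229). That of Cdkn1c was kept only without replicate 1 of either genotype (up to 0.251). With all ages in 1 fit the calls of Kit, Syce2, Cdkn1c, Zim1, Rasgrf1 and Zscan4a all ended (adjusted p of 0.309, 0.168, 0.277, 0.123, 0.388 and 0.153). Adjusted over the list alone, 2 recombination repair genes rose and 1 fell, and the other counts here were the same. With directional fry only heterochromatin passed (adjusted p = 0.0286). With mixed fry the piRNA pathway (adjusted p = 0.00456), heterochromatin (0.00809), homologous recombination repair (0.0171) and cleavage-stage genes (5.4e-05) passed. Outside these lists, interferon and nucleic acid sensing passed with mixed fry (adjusted p = 0.0386).

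Among markers of other cell types at e18.5, 2 of 8 macrophage and white blood cell genes rose. Mrc1, a mannose receptor, rose 3.34-fold (22.5 ± 5.402 to 75.3 ± 8.26 CPM, adjusted p = 1.5e-05), and Adgre1, the F4/80 antigen, 3.52-fold (3.99 ± 0.598 to 14.1 ± 1.81 CPM, adjusted p = 0.00109; 0.397 with all ages in 1 fit). The list passed with the preset correlation (adjusted p = 0.0125; adjusted p = 0.741 with an estimated correlation). It passed with mixed fry (adjusted p = 0.00382) but not with directional fry (adjusted p = 0.366). Its genes summed to 63.0 to 95.5 CPM in heterozygous and 131 to 162 in knockout libraries. In the stroma list 1 of 17 genes rose, Dcn, a matrix proteoglycan (1.81 ± 0.808 to 5.97 ± 1.24 CPM, adjusted p = 0.0434), a call kept only without heterozygous replicate 3 among fits without 1 library (adjusted p of up to 0.218) and ended with all ages in 1 fit (adjusted p = 0.104). The number of lists past the threshold, 2, was 1 without heterozygous replicate 2 or knockout replicate 3 and 4 without knockout replicate 1.

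Repeat families at e18.5 split by kind. The L1 family rose 1.78-fold, from 308219 ± 89179 to 549368 ± 44936 CPM of gene counts (adjusted p = 6.6e-05), and ERV1 retroviruses rose 1.81-fold (adjusted p = 7.5e-05). The ERVK family, which holds IAP and MusD, rose 1.44-fold (adjusted p = 0.0370). The Satellite family fell 2.48-fold, from 8362 ± 2362 to 3367 ± 338 CPM (adjusted p = 2.0e-09; 0.0981 with the repeats' own TMM factors). The ERVK call ended without heterozygous replicates 1 or 2 and without knockout replicates 1 or 2 (adjusted p of up to 0.354), with the replicate block (adjusted p = 0.102) and with the repeats' own totals (adjusted p = 0.267), where the log2 fold change went from 0.52 to 0.13. Of 1130 repeat names 85 rose and 4 fell. The count of 89 was 55 without heterozygous replicate 1, 51 without heterozygous replicate 2 and 51 without knockout replicate 1. With the repeats' own TMM factors 143 names rose and 35 fell, and with their own totals 124 rose and 59 fell. With own TMM factors 4 families rose and 0 fell, and with own totals 2 rose and 32 fell.

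Single retrotransposons at e18.5 rose by up to 6.92-fold, in IAPLTR4_I (21.5 ± 6.23 to 148 ± 15.5 CPM, adjusted p = 1.0e-27). IAPLTR1_Mm rose 3.84-fold and IAPEY3-int 2.78-fold, and the added IAPEz-int rose 2.10-fold (512 ± 45.1 to 1078 ± 12.5 CPM). Of the young L1 names L1Md_Gf rose 3.23-fold, L1Md_T 2.75-fold (9392 ± 4422 to 25845 ± 3333 CPM), L1Md_A 2.64-fold, L1Md_F 2.53-fold and L1Md_F2 2.24-fold. With the repeats' own TMM factors or totals the calls of L1Md_T (adjusted p = 0.0515 and 0.0581) and L1Md_A (adjusted p = 0.0547 and 0.0627) ended, at log2 fold changes of 1.28 to 1.39. ETnERV-int rose 2.53-fold, MMERVK10C-int 2.90-fold, MuRRS-int 2.68-fold, RLTR4_MM-int 2.61-fold and MMERGLN-int 2.47-fold. IAP-d-int rose 1.54-fold, a call kept only without heterozygous replicate 3 among the fits without 1 library (adjusted p of up to 0.183). Of 173 other retroviral names 35 rose and 1 fell, of 174 DNA transposon names 1 rose, and of 31 SINE names 0 passed. Of 100 older L1 names, a set added after seeing the data, 5 rose. Of 4 satellite names 1 rose and 1 fell. The median of all repeat names was 0.11 on the log2 scale with gene scaling and -0.02 when the repeat counts set their own scaling. Relative to the median of all repeats, young L1 names lay 1.26 and IAP names 0.97 higher. The share of all counts in repeats did not differ beyond the spread (2.70 percentage points higher, exact permutation p = 0.5, two-sided). The shares in young L1 (1.64% ± 0.587 to 3.79% ± 0.489) and IAP (0.160% ± 0.00733 to 0.312% ± 0.0240) separated the genotypes with exact permutation p = 0.1, the smallest that 3 against 3 allows.

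**Figure D3:**
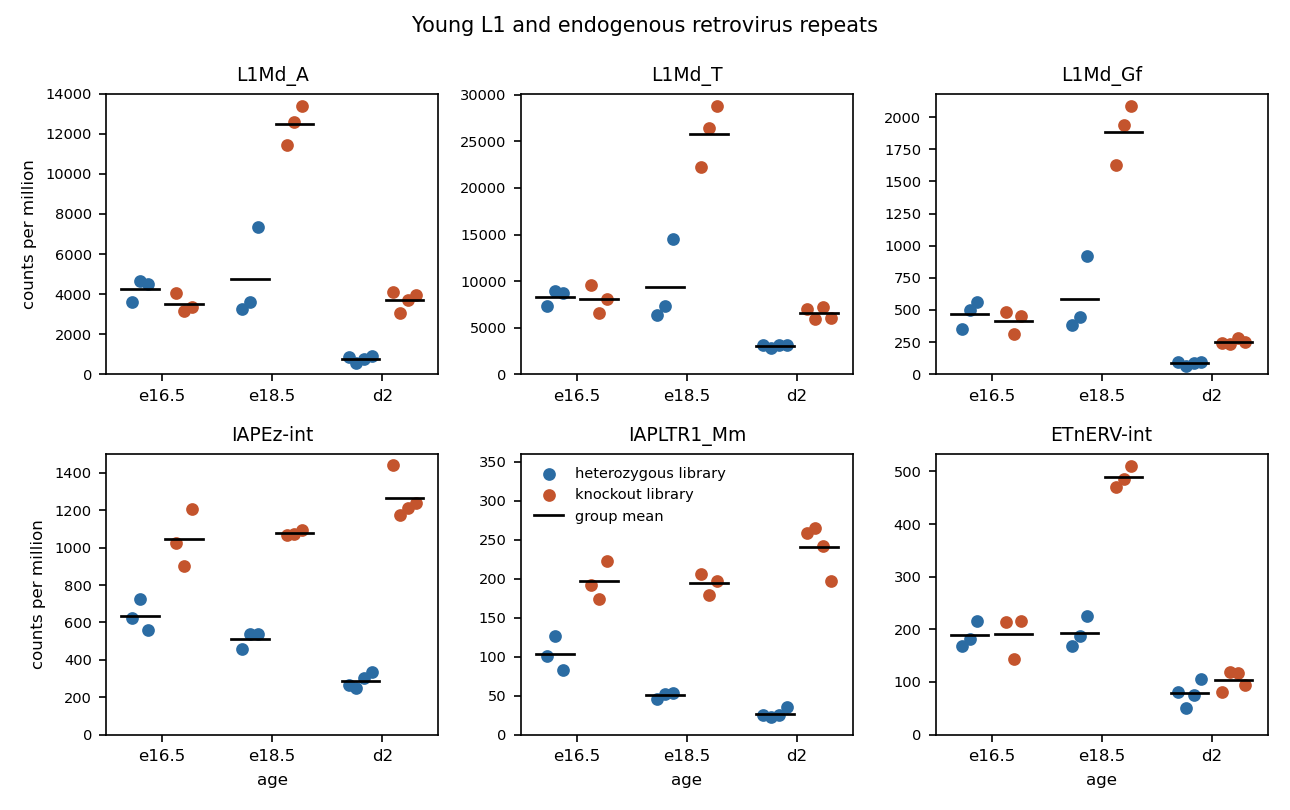
Level of 6 repeat names (CPM of gene counts, linear axis) in each library by age, 1 point per library and 1 colour per genotype. L1Md_A averages 781 CPM in heterozygous and 3700 in knockout cells at d2, and 4249 and 3523 at e16.5.

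At d2 young L1 and IAP retrotransposons rose in knockout cells (5 of 6 and 12 of 16 names). Of 15343 genes, 311 rose and 119 fell. IAPEz-int rose 4.40-fold, from 288 ± 40.1 to 1266 ± 120 CPM (SD, n = 4; adjusted p = 3.1e-27), and L1Md_A 4.74-fold, from 781 ± 166 to 3700 ± 464 (adjusted p = 4.4e-30). Sycp1, of the synaptonemal complex, rose 2.05-fold, from 224 ± 30.7 to 461 ± 129 CPM (adjusted p = 0.00222). The count of 430 was 770 with DESeq2 and also 770 with all ages in 1 fit, 235 with the replicate block (199 higher, 36 lower), 219 without heterozygous replicate 1, 187 without knockout replicate 1, 209 without knockout replicate 3 and 235 without knockout replicate 4, and it was 573 without knockout replicate 2, the library with Tex15 reads.

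Several of the genes with the largest increases at d2 are known from tissues other than the testis. Cyp4a12b, a cytochrome P450 of a near-identical family whose reads may be shared, had 0 counts in heterozygous and 813 in knockout libraries, at least 307-fold more against 3 counts over the group. Reg2, a secreted protein of the pancreas, was at least 80.3-fold higher, AA792892 at least 68.6-fold, and the odorant receptors Olfr792 and Olfr559 at least 57.3-fold and 49.8-fold. The bile salt transporter gene Abcb11 had 2 counts against 252 (ratio 143, 95% counting interval 39.1 to 1184), and the pheromone receptor Vmn1r195 had 2 against 367 (ratio 208, 57.1 to 1721). Gnat3, a G protein of taste cells, rose from 0.427 ± 0.663 to 71.9 ± 16.3 CPM (adjusted p = 3.3e-06). The cadherin Cdh19 rose from 0.327 ± 0.110 to 49.4 ± 24.9 (adjusted p = 4.7e-09), and Apoh, a plasma glycoprotein of the liver, from 0.393 ± 0.671 to 24.9 ± 6.81 (adjusted p = 3.5e-05). Without 1 library the log2 fold change of Gnat3 ran from 6.97 to 9.41 and that of Apoh from 5.63 to 8.39.

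Of the 10 largest decreases at d2, H2-D1, a class I histocompatibility gene, fell 3.13-fold (13.2 ± 2.14 to 4.22 ± 1.09 CPM, adjusted p = 0.00670) and Srrm4, a splicing factor of neurons, 3.23-fold (29.4 ± 15.9 to 9.10 ± 2.73 CPM, adjusted p = 0.0120), and both calls held in all fits without 1 library. The replicate block ended the call of Srrm4 (adjusted p = 0.0537) but not that of H2-D1. Lrtm1, Slc28a3, Nobox, Mybpc2, Pcdhgc5, Scn4a, Kif19a and Upk1b fell with log2 fold changes from -2.45 to -1.73. All 8 calls ended in some of the 8 fits without 1 library: Mybpc2 in all 8, Nobox in all but that without heterozygous replicate 2, and Slc28a3 in all but that without knockout replicate 2. Lrtm1 kept its call only without replicate 2 of either genotype, Kif19a only without heterozygous replicate 4 or knockout replicate 2, and Pcdhgc5 and Scn4a only without heterozygous replicates 2 or 4 or knockout replicate 2. Upk1b lost its call without heterozygous replicate 4 and without knockout replicates 1, 3 or 4. The highest adjusted p in these fits was 0.148, 0.146, 0.146, 0.104, 0.0934, 0.134, 0.101 and 0.150 for Mybpc2, Nobox, Slc28a3, Lrtm1, Kif19a, Pcdhgc5, Scn4a and Upk1b. Of these 8 only Scn4a kept its call with the replicate block, where the highest adjusted p was 0.128, for Nobox.

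**Figure D4:**
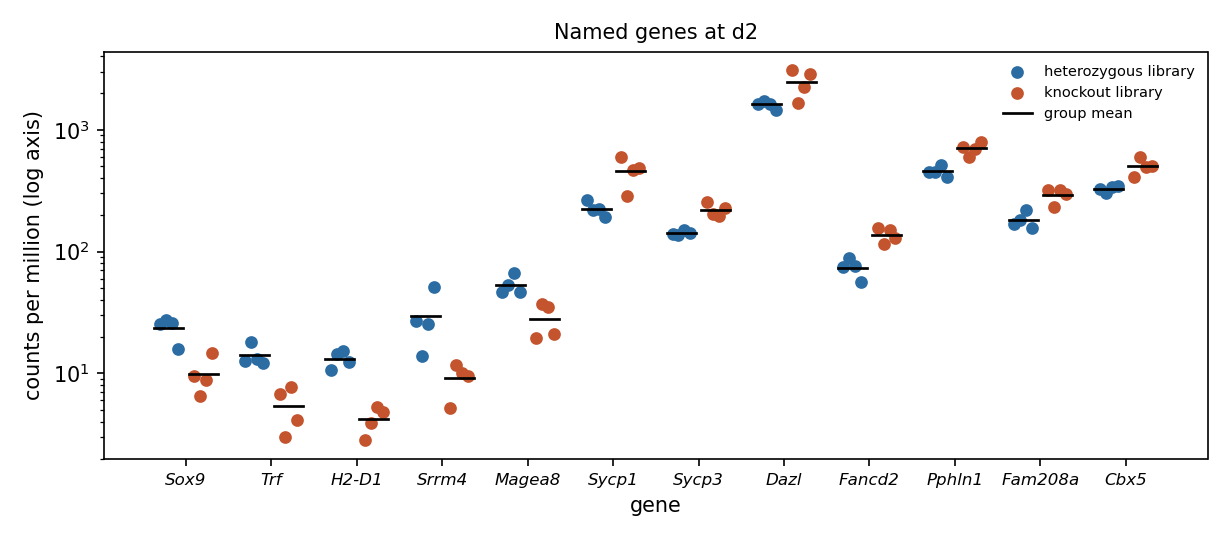
Level of 12 genes at d2 (CPM, log axis) in each heterozygous and knockout library, with the mean of each group of 4. Sycp3 averages 142 CPM in heterozygous and 221 in knockout cells, and Sox9 averages 23.8 and 9.90.

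In heterochromatin and histone-based repeat silencing 4 of 20 genes rose at d2. Pphln1 (457 ± 43.6 to 704 ± 83.4 CPM, adjusted p = 0.00418) and Fam208a (182 ± 27.1 to 293 ± 41.4, adjusted p = 0.00732) encode parts of the HUSH silencing complex. Cbx5 rose 1.52-fold (adjusted p = 0.00775), and Suv39h2, a histone H3 methyltransferase, rose 1.74-fold (adjusted p = 0.0118). The list passed with the preset correlation (adjusted p = 0.00315; adjusted p = 0.741 with an estimated correlation), and the same number rose adjusted over the list alone. Of 29 meiotic prophase genes 2 rose, Sycp1 and Sycp3 (142 ± 5.50 to 221 ± 27.1 CPM, adjusted p = 0.00569), and 7 rose adjusted over the list alone. That list passed with the preset correlation (adjusted p = 0.00539; adjusted p = 0.741 with an estimated correlation). In homologous recombination repair 1 of 21 rose, Fancd2 (73.8 ± 13.8 to 138 ± 18.96 CPM, adjusted p = 0.00225), and 2 adjusted over the list alone (list adjusted p = 0.0411; adjusted p = 0.756 with an estimated correlation). Cell proliferation passed (adjusted p = 0.000499; adjusted p = 0.834 with an estimated correlation) with 0 of 35 members past the threshold. Its mitotic checkpoint gene Bub1 measured 202 ± 41.6 against 297 ± 54.6 CPM (adjusted p = 0.0745, and past the threshold without replicate 2 of either genotype, with DESeq2, with voom weights and with the stroma covariate, down to 0.0138, and up to 0.205 without knockout replicate 4), and Ccne2 17.8 ± 1.88 against 26.5 ± 3.43. Without heterozygous replicate 4 the number of lists past the threshold was 2 in place of 4. No list passed at d2 with directional fry. With mixed fry heterochromatin (adjusted p = 0.00382) and meiotic prophase (0.0171) passed. So did germline genes with methylation-controlled promoters (0.0316) and Sertoli markers (0.0171).

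Germline genes with methylation-controlled promoters went both ways at d2: Sycp3 and Dazl, an RNA-binding protein of germ cells, rose, and Magea8 and Dpep3 fell, 4 of 25. Dazl rose 1.52-fold (1614 ± 116 to 2462 ± 645 CPM, adjusted p = 0.0349) and Magea8 fell 1.90-fold (adjusted p = 0.0279). The list did not pass (adjusted p = 0.516), and 5 of its members rose and 2 fell adjusted over the list alone. Dazl was also the 1 of 16 fetal prospermatogonia genes that rose, and 2 rose adjusted over that list alone. Ifi44, an interferon-induced gene, rose 6.34-fold (1.28 ± 1.57 to 8.12 ± 2.65 CPM, adjusted p = 0.0421), 1 of 20 in its list, and its log2 fold change of 2.66 ran from 2.29 to 3.76 without 1 library. Of 16 Sertoli cell genes 2 fell, Sox9, their sex-determining factor (23.8 ± 5.27 to 9.90 ± 3.47 CPM, adjusted p = 0.0189), and Trf, transferrin (14.1 ± 2.82 to 5.401 ± 2.19 CPM, adjusted p = 0.0290). Sertoli markers summed to 140 to 174 CPM in heterozygous and 115 to 167 in knockout libraries. Rpl3 fell 2.64-fold (adjusted p = 0.0358), 1 of 44 ribosomal protein genes. Without 1 library, Dazl kept its call only in the fits without replicate 2 of either genotype, Ifi44 only without heterozygous replicate 4, Trf only without heterozygous replicate 4 or knockout replicate 3, and Rpl3 only without replicate 4 of either genotype. Sox9 lost it without replicates 1 or 3 of either genotype, and Magea8 without heterozygous replicates 1 or 3 or knockout replicates 1 or 4. The highest adjusted p in these fits was 0.141 for Dazl, 0.111 for Ifi44, 0.0988 for Trf, 0.118 for Rpl3, 0.0678 for Sox9 and 0.114 for Magea8. The replicate block ended all of these calls but that of Magea8 (adjusted p of up to 0.0962), and all ages in 1 fit ended that of Rpl3 (adjusted p = 0.436).

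Repeat families that rose at d2 were L1, 1.61-fold (adjusted p = 0.00454), ERVK, 1.497-fold (adjusted p = 0.0156), and ERV1, 1.42-fold (adjusted p = 0.0317). The Satellite family measured 1692 ± 127 CPM in heterozygous and 2255 ± 281 in knockout cells and did not pass (adjusted p = 0.120; 0.0176 without knockout replicate 2, 0.0277 with DESeq2, 0.00712 with the replicate block, and up to 0.714 with the repeats' own totals). With the repeats' own totals the ERV1 log2 fold change went from 0.51 to 0.17 and its call ended (adjusted p = 0.0595). No family passed without heterozygous replicate 1 or without knockout replicate 3, and L1 was the only one without heterozygous replicates 2 or 3 or knockout replicates 1 or 4. Without knockout replicate 2, 5 families passed. Of 1081 repeat names 92 rose and 1 fell, and 154 passed without knockout replicate 2 and 188 with the replicate block (183 higher, 5 lower). With the repeats' own TMM factors 95 names rose and 20 fell. With their own totals 89 names rose and 16 fell, and 2 families rose and 24 fell.

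Most of the 12 single retrotransposons with the smallest p at d2 were IAP and L1 names, and the rest were RLTR names. IAPLTR1_Mm rose 9.02-fold (26.7 ± 5.73 to 240 ± 31.1 CPM, adjusted p = 3.8e-49), IAPLTR2a 5.28-fold, IAPLTR2b 4.10-fold and IAPLTR2_Mm 2.36-fold. L1Md_Gf rose 2.92-fold, L1Md_T 2.13-fold, L1VL1 2.14-fold and L1Md_F2 1.81-fold, and RLTR10A, RLTR46 and RLTR1B-int rose 2.72-fold, 2.51-fold and 2.23-fold. IAP-d-int did not pass (log2 fold change 0.24). By group, 5 of 6 young L1, 12 of 16 IAP, 2 of 5 MusD and ETn and 3 of 3 satellite names rose, as did 29 of 170 other retroviral, 3 of 168 DNA transposon and 23 of 99 older L1 names, and 0 of 7 MERVL and 0 of 31 SINE names passed. Of the satellite names GSAT_MM (26.9 ± 15.9 to 54.9 ± 10.1 CPM, adjusted p = 9.4e-05) lost its call with DESeq2 (adjusted p = 0.0975) and with the repeats' own totals (adjusted p = 0.0599). Relative to the median of all repeats (0.20 with gene scaling, -0.01 with the repeats' own), young L1 names lay 0.88 and IAP names 0.72 higher on the log2 scale. Young L1 took 0.626% ± 0.0640 of all counts in heterozygous and 1.16% ± 0.0586 in knockout cells, and IAP 0.119% ± 0.0115 and 0.221% ± 0.0111. The 2-sided exact permutation p was 0.0286 for both, the smallest that 4 against 4 allows, and 0.129 after adjustment over 9 such tests. The share of all repeats did not differ beyond the spread at d2 (exact permutation p = 0.4, two-sided) or at e16.5 (p = 0.3, exact permutation).

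Lists with no call at any age were tested in the same way. In DNA methylation machinery 0 of 13 genes passed at each age (adjusted p = 0.744, 0.658 and 0.778 at e16.5, e18.5 and d2). The list of spermatogonial stem and progenitor cells had 0 genes past the threshold (adjusted p = 0.0764, 0.0767 and 0.993), as had p53 targets and apoptosis (0.516, 0.744 and 0.713), dissociation and stress genes (0.744, 0.744 and 0.368) and spermiogenesis and post-meiotic genes (0.744, 0.752 and 0.993). So had the Leydig (0.206, 0.659 and 0.709), endothelial (0.744, 0.659 and 0.744) and red blood cell markers (0.744, 0.384 and 0.898). Adjusted over the list alone, 1 endothelial gene rose and 1 spermiogenesis gene fell at d2, and 0 of the others passed. With mixed fry p53 targets and spermiogenesis genes passed at d2 (adjusted p = 0.00382 for both). Red blood cell markers did so at e18.5 (adjusted p = 0.00509). Mitochondrially encoded genes were not listed in the deposited counts.

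Whether the same genes responded at e18.5 and d2 was tested on the 14780 genes measured at both ages. Of 184 that rose at e18.5 and 301 that rose at d2, 60 rose at both, where 3.75 would be shared by independent lists (odds ratio 28.8, Fisher's exact p = 1.6e-56). Of 45 and 116 that fell, 2 were shared (Fisher's exact p = 0.0486, 0.146 adjusted over 6 tests). No gene passed in the same direction at all 3 ages. Of the 184 genes 145 were higher at d2 too, passed or not, and of the 301 genes 185 were higher at e18.5. Among all genes that rose, 126 at e18.5 and 56 at d2 lay under 1 CPM in heterozygous cells. Genes that low were tested mainly where their knockout counts passed the filter, which favours a rise at both ages. Neighbouring genes can also share reads and are then not independent. The odds ratio and p of the shared increases may thus overstate the overlap.

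The knockout effect itself differed between ages in 162 of 18619 genes in 1 fit to all 20 libraries, tested over all 3 ages at once (471 with DESeq2 and 104 with the replicate block). Between e16.5 and e18.5 the difference passed in 18 genes, between e18.5 and d2 in 98, and between e16.5 and d2 in 149, of which 132 had the higher effect at d2. Gtsf1 went from 60.7 against 85.6 CPM at e16.5 to 86.1 against 28.1 at e18.5 and 92.1 against 68.4 at d2, heterozygous against knockout. Tmc2, a channel protein of inner ear hair cells, rose 4.91-fold at e18.5 and 13.8-fold at d2, while its log2 fold change at e16.5 was -0.37. Samd9l, an interferon-responsive gene, measured 3.999 ± 1.67 CPM in heterozygous and 80.1 ± 10.6 in knockout cells at d2, and 18.7 ± 4.02 and 24.4 ± 6.16 at e18.5. Among families, the difference between e16.5 and e18.5 passed in L1 and ERV1, which moved up, and in Satellite, which moved down.

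The heterozygous libraries were compared for the change with age when 1 copy of Tex15 works. Library batches by age, if any, cannot be told apart from age in these comparisons. From e16.5 to e18.5, 1420 genes rose and 1893 fell. In the piRNA pathway 15 of 25 genes fell and 1 rose, and 16 fell and 1 rose adjusted over the list alone. Morc1 fell 2.23-fold (898 ± 139 to 403 ± 7.46 CPM), Asz1 2.39-fold and Pnldc1 2.15-fold, and the list passed with both settings (adjusted p = 1.4e-07; adjusted p = 0.0313 with an estimated correlation). Dppa3, a maternal and germ cell factor, fell 22.4-fold, from 350 ± 348 to 15.6 ± 0.963 CPM (SD, n = 3), and Khdc1a 19.6-fold, Ifitm2 11.3-fold, Cyp4a12b 7.03-fold, Pfas 6.33-fold and Foxr1 5.50-fold. St8sia3 rose 14.8-fold (7.94 ± 1.303 to 118 ± 8.87 CPM), the protocadherin Pcdh7 9.03-fold, Klhl14 8.28-fold, Amy1 7.96-fold, Soga3 7.72-fold and Adam5 7.53-fold. The total of 3313 was 1740 without replicate 1 and also 1740 without replicate 2 of the e16.5 heterozygous libraries.

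Other lists fell or rose with age by the preset correlation from e16.5 to e18.5. Homologous recombination repair fell in 8 of 21 genes, among them Fancd2, 3.35-fold (list adjusted p = 8.2e-05). Heterochromatin fell in 8 of 20 genes, among them Cbx5, 1.84-fold (list adjusted p = 0.000463). Both had an adjusted p = 0.378 with an estimated correlation. Cell proliferation fell in 10 of 35 and rose in 1, the cyclin Ccne1 (list adjusted p = 8.2e-05; adjusted p = 0.643 with an estimated correlation). Ribosomal proteins fell in 12 of 45 (list adjusted p = 6.5e-06; adjusted p = 0.557 with an estimated correlation), and endothelial markers rose in 3 of 13 (list adjusted p = 0.00434; adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone, 12 repair genes, 10 heterochromatin genes, 13 proliferation genes and 21 ribosomal protein genes fell, and 4 endothelial genes rose. No other list measured passed.

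From e18.5 to d2, spermatogonial genes rose in heterozygous cells, 16 of 28, with 2 that fell. The receptor genes Gfra1 and Ret rose 23.4-fold (10.6 ± 0.749 to 247 ± 35.9 CPM) and 15.8-fold (32.5 ± 0.801 to 512 ± 95.9 CPM), and Egr2 rose 23.4-fold. Cell division genes rose in 31 of 35, among them Cdc6, 12.9-fold, and Rrm2, 13.2-fold. Both lists passed with the preset correlation (adjusted p = 3.7e-08 and 9.0e-11; adjusted p = 0.166 and 0.496 with an estimated correlation). Dissociation and stress genes rose in 12 of 22, with Egr1 16.1-fold (62.6 ± 6.996 to 1010 ± 91.0 CPM), and passed with both settings (adjusted p = 0.000262; adjusted p = 0.0313 with an estimated correlation). Of p53 targets 11 of 22 rose, with Cdkn1a 14.5-fold (list adjusted p = 0.0458; adjusted p = 0.307 with an estimated correlation). Ribosomal protein genes rose in 20 of 45 and fell in 4 (list adjusted p = 0.00434; adjusted p = 0.643 with an estimated correlation). Adjusted over the list alone, 17 spermatogonial, 31 proliferation, 13 stress, 12 p53 and 23 ribosomal protein genes rose. In all 4494 genes rose and 5030 fell. The d2 libraries were counted on a different set of gene definitions, so that age and counting cannot be told apart for single genes: Cmtr1 (94.1-fold), Scamp3 (73.7-fold) and Adnp (57.9-fold) are among the largest increases, with Hs3st3b1 and Foxc2. The largest decreases were in Serpina3c, Cyp4a12b, Olfr695, Abcb11, Frmpd3 and Mia2. Of 51 repeat families 42 fell and 0 rose, relative to gene counts.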

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

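In this part, the tests of a wrong label and of the satellite counts were chosen only after the result was seen, and the test of satellite scaling replaced an earlier form that had left scaling open.

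In the d2 groups of 4 libraries, 110 sets of values were searched for a library far from the other 3, and 7 held one, where chance gives about 1 in 20. Tex15 in knockout replicate 2 was 104 CPM. Heterozygous replicate 4 stood apart in Upk1b (19.7 CPM) and Apoh (1.40 CPM), and heterozygous replicate 3 in Vmn1r195 (0.234 CPM). Heterozygous replicate 2 stood apart in total count (24.8 M, mega), IAPLTR2a (46.0 CPM) and L1Md_T (2839 CPM).

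Knockout replicate 2 at d2 held Tex15 at 104 CPM, against 2.07 to 2.62 in the other 3 knockout libraries. On Tex15 alone the library was unlike an unmixed heterozygous one, at 16.5% of the lowest heterozygous value of 633 CPM. That value is the one that raised the question, and the limit was set after it was known. It is thus no independent test, and a wrong label is not decided by it. Heterozygous cells or RNA in the library could be the source: over 60 genes high in the other knockout libraries and near silent in heterozygous ones, its median log2 ratio to them was -0.35 (SE 0.14), lower than when the other 3 were left out in turn (-0.24, -0.20 and 0.08), where its Tex15 level would give a shift of -0.19. The gap to the next library is under 1 SE, so the test carries little weight. An earlier form of the label test, replaced after it was run, put replicate 2 on the knockout side in 57.0% of 572 genes, against 91.4%, 90.4% and 85.1% for the others left out alike.

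Satellite counts fell in knockout cells at e18.5 (log2 fold change -1.31, SE 0.19), and the single name GSAT_MM, the major satellite, measured 14438 to 30545 CPM in heterozygous and 1117 to 4036 in knockout libraries (adjusted p = 0.0979; past the threshold with DESeq2, 2.0e-05, with the replicate block, 7.5e-51, and without heterozygous replicate 2, 3.8e-12, or knockout replicate 1, 1.2e-34, and up to 0.344 without heterozygous replicate 1), while at e16.5 it measured 533 to 12488 and 27.0 to 113 CPM (adjusted p = 0.373) and at d2, where it rose, 15.8 to 50.3 and 44.6 to 68.8 CPM. That 1 library made the difference is argued against, since the highest adjusted p of the family in the 6 fits without 1 library was 3.3e-05. Scaling between the libraries is argued against, since it moves all families alike while the satellite change lay below the median of the other 50 families by a log2 gap of -1.40 (lowest other family -0.15), and with the repeats' own TMM factors it went from -1.31 to -1.46, where the call ended as the SE rose from 0.19 to 0.35 (adjusted p = 0.0981). Genomic DNA in the heterozygous libraries stays open. The old families L2, MIR and Charlie had a median change of 0.081 but counts of up to 13937 CPM. The excess of the Satellite family was 4995 CPM, so that added DNA might not show in them. The single name GSAT_MM averaged 24391 CPM in heterozygous and 2150 in knockout libraries, while the whole Satellite family averaged 8362 in heterozygous ones. The name and family counts thus measure satellites differently, and the size of the excess depends on which is used. An effect of the genotype cannot be told apart from added DNA and was not tested further.

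The knockout effect differed between ages in 162 genes. From e16.5 to e18.5 the difference of log2 fold changes was -2.13 for Gtsf1, -1.58 for Abca1, 2.65 for Tmc2, -1.34 for Insig1 and -1.43 for Fsd1l. From e18.5 to d2 it was 3.96 for Samd9l, 3.97 for Cdh12, 2.92 for Atp13a5, 7.83 for Cyp4a12b and 5.76 for Gnat3. From e16.5 to d2 it was 4.46 for Samd9l, 5.83 for Cdh12, 6.85 for Abcb11, 9.67 for Cyp4a12b and 5.04 for 4930558C23Rik, where d2 also differs in the gene definitions used. Among families it was -0.84 for Satellite, 1.03 for L1 and 0.85 for ERV1 from e16.5 to e18.5, 1.73 for Satellite from e18.5 to d2, and 0.89 for Satellite, 0.89 for L1 and 0.66 for ERVK from e16.5 to d2.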

How the results depend on the processing

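Of the values of single named genes and repeats under all alternatives, 1572 kept their direction and side of the threshold, 19 passed only under the alternative, 226 no longer passed and 8 turned in direction. Past the threshold and the same under all alternatives were 29 of 50 named items at e18.5, 30 of 49 at d2 and 0 of 4 at e16.5. The cause was not tested for any change below, save that fits without 1 library have fewer samples.

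DESeq2 called 22 genes at e16.5, 770 at d2 and 471 whose knockout effect differed between ages, and gave Tex15 at d2 -4.93 (past the threshold). All ages in 1 fit gave 0, 152 and 770 genes at e16.5, e18.5 and d2, and Tex15 -8.80 at e16.5 (not past the threshold) and -4.97 at d2 (past it). Tex15 at d2 also passed with voom weights (-7.66) and with the stroma covariate (-7.65). With no filter 2 genes were called at e16.5, 1 repeat name at e16.5 and 4 lists at e18.5. The replicate block gave 235 genes, 5 families and 188 repeat names at d2, 1 repeat name at e16.5 and 104 genes differing between ages. Whether the numbers pair the libraries stays open. At e18.5 each heterozygous library correlated best with the knockout library of its own number, but only weakly (r from 0.053 to 0.105). At e16.5 and d2 most did not. With the repeats' own TMM factors 1 family was called at e16.5 and 178 repeat names at e18.5. With their own totals 1, 34 and 26 families were called at e16.5, e18.5 and d2, and 183 repeat names at e18.5. With an estimated correlation 0 lists passed at each age.

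At e16.5 the log2 fold change turned for Col3a1 with the stroma covariate (0.0078), L1Md_F2 with the repeats' own TMM factors (0.078) and totals (0.045), L1Md_A with own TMM factors (0.016), and IAP-d-int with own TMM factors (0.17), own totals (0.14), without heterozygous replicate 2 (0.018) and without knockout replicate 2 (0.058). Without 1 library IAP-d-int ran from -0.31 to 0.058.

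Without 1 library, the lowest and highest values at e16.5, e18.5 and d2 were 1 to 25, 274 to 502 and 187 to 573 genes, 0 to 1, 3 to 4 and 0 to 5 families, 0 to 6, 51 to 91 and 66 to 154 repeat names, and 4 to 12, 1 to 4 and 2 to 5 lists. Tex15 ran from -9.01 to -8.70, -9.36 to -8.67 and -8.45 to -4.56, and the difference in repeat share from -7.99 to -3.02, 0.783 to 4.09 and 0.567 to 3.65 percentage points. The overlap ran from 47 to 72 genes, the genes and families differing between ages from 109 to 227 and 2 to 4, and the heterozygous age changes from 1740 to 4077 and 8249 to 9833. Depth limits changes in genes with few counts. In simulated genes with a mean log2 CPM of at least 1, 2-fold changes were recovered in 49.0% to 59.6%. Recovery in genes with fewer counts was not measured.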

Other observations

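In this part, the tests of sterol genes and of macrophages were chosen only after the result was seen, and the receptor families were counted after it.

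Insig1 and Lss, genes of sterol synthesis, fell in knockout cells at e18.5 and d2. Insig1, a regulator of sterol synthesis, fell at e18.5 (126 to 55.9 CPM, adjusted p = 0.000730) and at d2 (276 to 166 CPM, adjusted p = 0.000829). Lss, the enzyme lanosterol synthase, fell at e18.5 (32.4 to 14.1 CPM, adjusted p = 0.0181) and at d2 (155 to 97.4 CPM, adjusted p = 0.00649). The cholesterol exporter gene Abca1 fell at e18.5 (299 to 152 CPM) and rose at d2 (162 to 231 CPM). These genes led to the hypothesis that other sterol genes may fall with them. Over 21 such genes, without Insig1, Lss and Stard4, the p with an estimated correlation was 0.0626 at e18.5 (median log2 fold change -0.43, 0 fell) and 0.000937 at d2 (median -0.48), where Dhcr7 and Srebf2 fell. At e18.5 the question stays open, and at e16.5 the median was 0.04.

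Of the genes that rose in knockout cells, 65 of 373 at e18.5 and 6 of 311 at d2 encode olfactory or pheromone receptors. Receptors made up 296 of the 18075 genes tested at e18.5 and 30 of 15343 at d2, and 0 fell. The lower count at d2 thus came with fewer receptor genes tested. Receptor genes near silent in heterozygous cells were tested only where their knockout counts passed the filter, so these counts are given without a test. Such genes lie in clusters, and a hypothesis was that neighbouring genes may rise together. Of the genes that rose, 83 at e18.5 and 45 at d2 had a tested neighbour that rose, where sets matched on expression gave medians of 14 and 12 (permutation p = 0.0001 for both, the smallest that 10000 draws can give). The sets were not matched for entry through knockout counts or for gene families. The p thus cannot be read as the strength with which neighbours rose together. Without the receptor genes the number with such a neighbour was 51 at e18.5, against a median of 10, and 45 at d2, against 12, of which 20 and 12 had a neighbour with the same name stem. The same limit holds for these. Overlapping, antisense and near-identical genes can share reads, so shared reads stay open for all of these neighbours. The higher number of genes that rose than fell was not a trend with gene length: 96.8% at e18.5 and 95.2% at d2 stayed higher after each library's length trend was removed.

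Mrc1 and Adgre1 rose at e18.5 in cells sorted by green fluorescence, per the labels a gate for germ cells. That macrophages were the source is argued against: 20 other macrophage genes, 6 of them in the list of the report and all with counts in heterozygous cells too, had a median log2 fold change of 0.13, where more than 0.87 was needed, and the most abundant, Lgmn (0.15), Ctsc (-0.27) and Fcer1g (-0.09), did not pass. Of the 20, F13a1 alone rose (1.80). White blood cells of another kind stay open, since Ptprc and Laptm5 had a mean change of 0.53 (each with an SE above 0.36). The Mrc1 and Adgre1 change may also follow the genotype, which was not tested apart from these.

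Other splits of the same libraries were run for each count. For 3 against 3 the 10 splits are too few for a share under 0.05. As many as the real count were found, the real split included, in 2 splits for genes at e16.5 (1 called, highest other 2), 10 for families (0, highest other 43), 2 for repeat names (3, highest other 694) and 2 for lists (7, highest other 8). At e18.5 it was 1 split for genes (422, highest other 4), families (4, highest other 0) and repeat names (89, highest other 2) and 4 for lists (2, highest other 4). For heterozygous cells from e16.5 to e18.5 it was 1 (3430 called when fitted alone, highest other 0). Of 35 splits at d2, only the real one gave as many genes (430 called, highest other 2), which argues against chance. That is the smallest share that 35 splits can give, so chance is not excluded. As many families were found in 4 splits (3 called, highest other 36), and as many repeat names in 2 (93 called, highest other 418). As many lists were found in 15 (4 called, highest other 8). These 3 counts do not argue against chance. For heterozygous cells from e18.5 to d2 the values likewise argue against chance (1 of 35, 8402 called when fitted alone, highest other 4601). Of 100 drawn splits for the differences between ages, only the real one gave as many genes (162, highest other 83), which argues against chance. As many families (3, highest other 41) were found in 9, which does not. The splits with 694 repeat names at e16.5 and 418 at d2 part libraries with low from those with high repeat shares. At e16.5 heterozygous replicate 1 and knockout replicates 1 and 2 stood against the rest. At d2 heterozygous replicates 1, 2 and 3 and knockout replicate 2 stood against the rest. This structure of the samples follows genotype only in part, so that it cannot be fully told apart from genotype in the repeat calls.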
